A study of Homo sapiens with 5 samples.

How the data were processed

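RNA was prepared with Trizol from the same number of BT474 cells per replicate, with RNA integrity numbers above 9.3, per the labels' protocols. Parental cells (2 libraries) and persister cells (3 libraries) shared a solvent level of 0.01% DMSO, and treatment began at 75% confluence. Libraries were made with a kit that does not keep strand and were each spread over 5 lanes of an Illumina HiSeq instrument (per the labels' protocols). Reads from a gene and from an overlapping or antisense neighbour therefore cannot be told apart.

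The submitters' processing notes name CASAVA 1.8, TopHat2 2.0.6, Cufflinks, Cuffdiff 2.0.2 and the genome build hg18, without their settings. The deposited values are 1 table of 18803 rows with gene names, transcript identifiers, an FPKM value for each group, a q-value and a fold change. The authors combined the libraries of each group into a single FPKM value per gene (fragments scaled to transcript length and library size), per the file headers. How libraries were scaled to each other is not given in the sources used here. The q-value was deposited by the authors as an adjusted p of their own comparison, and its adjustment is not stated. It was listed as 0 in 2712 rows, and the smallest value above 0 was 1.2e-15. The fold change deposited by the authors is the ratio of persister to parental FPKM, given as text in 935 rows, and it was used here only to find rows without an estimate.

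The table holds no counts and no values per library. The total depth, the spread between replicates and the counting error are thus unknown, and no interval, SD or detection limit was computed. The planned test on values per library could not be made. As set out beforehand for this case, a gene was called when the authors' q-value was under 0.05, among genes that their test covered (q-value below 1). Those genes reached at least 0.0656 FPKM in 1 or both groups, so most of the others were too low to be tested. In 145 rows the fold was set to 1 and the q-value to 1 although the FPKM values differed (beyond a tolerance of 0.6%). These rows were taken as having no estimate. A value of exactly 0 in both groups was found in 1527 rows, some of them genes used by every cell, so such a value is described only as listed at 0. The sum of FPKM was 333324 in parental and 260213 in persister cells.

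Gene symbols were taken from the table. In 26 rows a spreadsheet date stood in place of the symbol, and 25 were given a symbol through their transcript identifiers, of which 18534 rows matched the reference annotation (GENCODE 29). The rows held 18512 symbols. Where a symbol stood on more than 1 row (269 symbols), the row with the highest mean FPKM was used. The reference was also used for transcript lengths, known for 98.1% of tested genes, and for the order of genes. Its build differs from that of the authors, and the table gives no positions, so no coordinates are given. BUB1B, GGT1, TXNRD3 and TET3, which belong to the lists, were not analysed here.

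Differences are log2(FPKM + 1) of persister minus parental cells. This pseudocount of 1 understates changes of genes with low values. The 31 gene lists, the rule for named genes, the test and the alternative settings were fixed before the data were examined. The lists cover mitosis, DNA replication, CDK inhibitors and p53 targets, ERBB receptors and ligands, MAPK output, FOXO-regulated genes, NRF2 targets, glutathione, other antioxidant enzymes, ferroptosis, epithelial, mesenchymal, luminal, basal and milk and secretory genes, cholesterol, fatty acid synthesis and oxidation, glycolysis, the respiratory chain, lysosome and autophagy, integrated stress and unfolded protein response, ribosome biogenesis, interferon, antigen presentation, the BCL2 family, stem cell and drug-tolerance markers, chromatin enzymes, and fibroblast, immune and endothelial markers, and 21 genes belong to more than 1 list. Named genes were 6 fixed ones (ERBB2, ERBB3, EGFR, GPX4, MKI67, ESR1), the 10 called genes with the largest rise and the 10 with the largest fall, and for each list up to 4 called members with the largest difference, or 2 by mean value where fewer than 2 were called. Any other gene named was chosen after its values were seen. Some genes that meet this rule, or that are counted among those without an estimate, are not reported here by name, and they remain in the counts.

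For each list, the share of members called higher and called lower was compared with that of the other tested genes by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over 62 tests and a threshold of 0.05. The median difference of a list was placed among the medians of 10000 random lists of the same size, drawn with replacement within 20 bins of mean FPKM. Fisher's exact test was not matched in this way, so a trend with mean FPKM can enter its p-values. For counts adjusted over the list alone, the p-value of each gene was approximated from its q-value and rank, assuming a Benjamini-Hochberg adjustment over the tested rows. The list tests were checked on simulated data from the 13617 tested genes: of 200 lists without an added change, 11 lay outside the central 95% of matched lists and 7 had a Fisher p under 0.05. Lists of 20 genes with an added difference of 0.25 were recovered in 5 of 10 cases, and with 0.5 or 1.0 in 10 of 10 cases. The simulated differences varied independently between genes, with a trend in mean FPKM but none in transcript length. Simulated calls were drawn at random without direction. The check therefore cannot give the error rate for lists of genes that vary together. Alternatives were a q-value of 0.01, a minimum difference of 1, FPKM minima of 1 and 5, centring on the all-gene median, a pseudocount of 0.1, and, chosen after seeing the data, every row of the table and random lists matched on transcript length as well. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.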

Results

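Polyadenylated RNA was sequenced from BT474 cells, an established HER2-amplified luminal breast cancer line, in 2 states. Persister cells were those remaining after 9 days in 2 µM lapatinib, an inhibitor of the HER2 and EGFR kinases, with the drug and medium renewed every 3 days. Parental cells were grown alongside in the same solvent without the drug. The persister group held 3 libraries and the parental group 2, which the submitters describe as biological replicates. The authors' deposited table gave a single FPKM value per gene for each group and a q-value for their comparison, so the values below are the authors' group values and carry no SD or n. The depth of each library is unknown, because the table holds neither counts nor values per library. The comparison asked which transcripts differed in the cells that survived the drug. There was no group treated briefly and none released from the drug. Direct effects of the drug, growth arrest and traits of surviving cells therefore cannot be told apart.

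Persister cells had far lower levels of transcripts for mitosis, DNA replication, MAPK output and sterol and fatty acid synthesis than parental cells. Transcripts under FOXO control, which are held down by active PI3K and AKT signalling, were higher, as was the receptor ERBB3. Secretory products of the mammary luminal cell were among the transcripts that fell most. Most antioxidant enzymes, among them GPX4, were lower. In the authors' deposited table, 9514 of the 13617 genes covered by the test (69.9%) had a q-value under 0.05, of which 4206 were higher and 5308 lower in persister cells. Of these, 406 were higher and 819 lower by at least 1 on the log2(FPKM + 1) scale, the scale of all differences below. The median difference over the 10160 genes with an FPKM of at least 1 in both groups was -0.12, and list medians are given relative to it. The replicate spread could enter only through the authors' own test, whose settings are not given. The difference also varied across genes with transcript length (Spearman's rho = 0.24) and with mean FPKM (Spearman's rho = -0.27) over 9976 genes, which are not independent replicates.

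**Figure D1:**
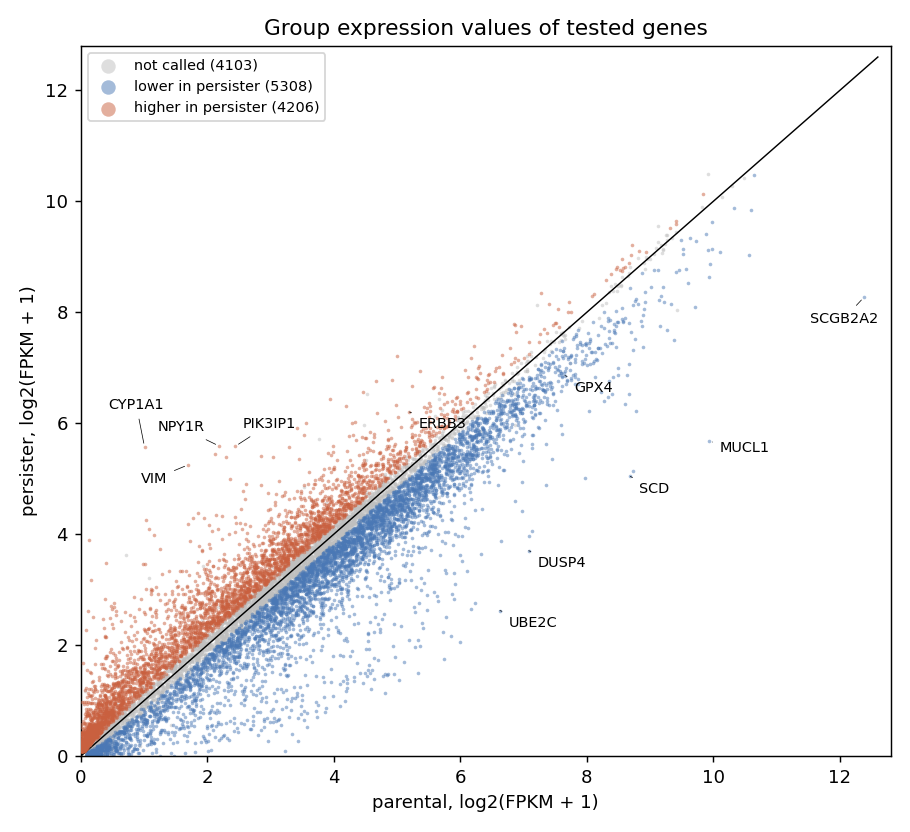
Authors' group values of the 13617 tested genes, with the parental value on the horizontal axis and the persister value on the vertical axis, both as log2(FPKM + 1). Each point is a gene, the line marks equal values, and colours mark the 4206 genes called higher, the 5308 called lower and the remaining genes, with MUCL1, SCGB2A2, SCD, UBE2C, DUSP4 and GPX4 below the line and CYP1A1, VIM, NPY1R, PIK3IP1 and ERBB3 above it.

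The largest rise among the called genes was that of CYP1A1, a cytochrome P450 enzyme induced through the aryl hydrocarbon receptor, from 1.01 to 46.7 FPKM. VIM, which encodes the intermediate filament vimentin, rose from 2.24 to 37.1 FPKM, and NPY1R, a neuropeptide Y receptor, from 3.55 to 47.2 FPKM. CALCOCO1 rose from 3.38 to 42.6 FPKM, and PIK3IP1, an inhibitor of PI3K, from 4.45 to 47.1 FPKM. The cell surface proteoglycan SDC2 rose from 3.94 to 40.9 FPKM, PGM5 from 0.317 to 10.2 FPKM and the collagen gene COL5A1 from 0.117 to 8.03 FPKM. PSG4 was listed at 0.0962 FPKM in parental and 13.9 FPKM in persister cells, a value made uncertain by the near-identical genes of its family. GTF2A1L was listed at 1.04 and 18.1 FPKM, and because it overlaps a neighbouring gene and the libraries did not keep strand, its source is uncertain.

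The largest falls were in secreted products and in genes of cell division. MUCL1, a small breast mucin, fell from 973 to 50.1 FPKM, and SCGB2A2, which encodes mammaglobin, from 5327 to 308 FPKM. The ubiquitin-conjugating enzyme UBE2C of the anaphase-promoting complex fell from 97.8 to 5.17 FPKM and CDC20, an activator of that complex, from 56.6 to 3.49 FPKM. PRR11 fell from 62.5 to 3.15 FPKM, CDKN3 from 39.2 to 1.84 FPKM and CEP55, a protein of the midbody, from 27.1 to 1.20 FPKM. Securin, encoded by PTTG1, was listed at 52.5 and 2.38 FPKM, with closely related copies that could share its reads. The chemokine CXCL17 fell from 31.6 to 1.60 FPKM. SCD, the desaturase that makes monounsaturated fatty acids, fell from 411 to 32.0 FPKM. Each of these 20 genes was called with a q-value listed as 0 in the authors' deposited table.

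**Figure D2:**
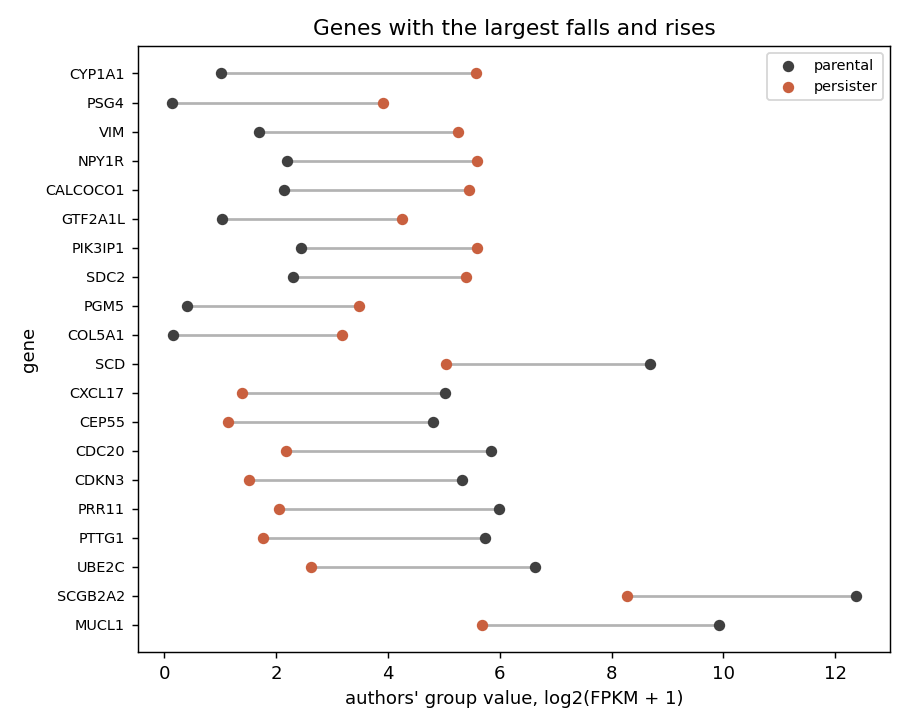
Authors' group values, as log2(FPKM + 1), of the 10 called genes with the largest rise and the 10 with the largest fall. Each row is a gene, dark points are parental and red points persister values, and the line between them is the difference, from CYP1A1 (1.01 to 46.7 FPKM) at the top to MUCL1 (973 to 50.1 FPKM) at the bottom.

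Every tested member of the mitotic and DNA replication lists fell. All 18 mitotic genes were called lower in the authors' deposited table, with a median of -3.19 (Fisher's exact test, adjusted p = 8.77e-07). The proliferation marker MKI67 fell from 12.5 to 0.887 FPKM, cyclin B1 (CCNB1) from 71.1 to 5.31 FPKM and its kinase CDK1 from 51.9 to 3.72 FPKM. All 22 replication genes were called lower as well, with a median of -1.79 (Fisher's exact test, adjusted p = 3.01e-08), among them RRM2, a subunit of ribonucleotide reductase, at 35.6 and 3.29 FPKM, and the replication licensing factor CDC6 at 20.4 and 1.84 FPKM. TK1 fell from 43.5 to 5.18 FPKM and CDC45 from 17.2 to 1.73 FPKM. Both medians lay below those of all 10000 random lists matched on mean FPKM. CDK inhibitors and p53 targets moved both ways, with 6 of 17 higher and 5 lower and a median of 0.18 (85.09th percentile). TP53INP1 rose from 17.9 to 53.8 FPKM, while the stress cytokine GDF15 fell from 38.1 to 2.93 FPKM and the CDK inhibitors CDKN2C from 8.45 to 1.29 FPKM and CDKN2D from 5.74 to 1.85 FPKM. Neither direction was enriched in that list (Fisher's exact test, adjusted p = 0.912 for higher and 0.675 for lower).

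Genes for MAPK output were mostly lower. FOXO-regulated genes, which active PI3K and AKT signalling holds down, were mostly higher, as were ERBB receptors and ligands. Of 17 genes for MAPK output and feedback, 15 fell and 1 rose, with a median of -0.99 (Fisher's exact test, adjusted p = 3.50e-04). The ERK phosphatases DUSP4 and DUSP6 fell from 135 to 12.02 FPKM and from 53.2 to 9.27 FPKM, the feedback inhibitor SPRY4 from 13.7 to 0.835 FPKM and the transcription factor ETV4 from 9.09 to 0.315 FPKM. Of 21 FOXO-regulated genes, 16 rose and 1 fell, with a median of 1.25, above all 10000 matched random lists (Fisher's exact test, adjusted p = 2.57e-04). Beside PIK3IP1, the ubiquitin ligase gene FBXO32 rose from 2.32 to 13.7 FPKM, the insulin receptor substrate gene IRS1 from 2.63 to 10.3 FPKM and CITED2 from 14.9 to 47.3 FPKM. Among ERBB receptors and ligands, 8 of 11 rose and 2 fell, with a median of 0.34 (98.23rd percentile, Fisher's exact test, adjusted p = 0.0154). ERBB3 rose from 35.7 to 72.7 FPKM, BTC from 1.23 to 2.00 FPKM, EGFR from 5.99 to 7.43 FPKM (q = 7.15e-04 in the authors' deposited table) and EPGN from 0.135 to 0.342 FPKM. The median of this list left the extreme 5% of matched lists with a pseudocount of 0.1 (88.81st percentile) or with genes under 1 FPKM removed (85.68th percentile), and 9.09% of its members were higher by at least 1, which did not pass. ERBB2 itself, the amplified gene encoding HER2, was listed at 0 in both groups, as was NRG1, and no change can be read for either.

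Antioxidant genes were mostly lower in persister cells. These lists were chosen with knowledge of published work on the same cells and are not independent evidence of direction. GPX4, the enzyme that reduces lipid peroxides, fell from 201 to 115 FPKM. Of 21 NRF2 targets, 15 fell and 4 rose, with a median of -0.44 (1.24th percentile, Fisher's exact test, adjusted p = 0.0106). AKR1B10 fell from 2.15 to 0.0456 FPKM, the NADPH-producing enzyme ME1 from 16.8 to 5.27 FPKM and the transporter ABCC3 from 53.5 to 25.9 FPKM. Of 19 other antioxidant enzymes, 15 fell and 0 rose, with a median of -0.44 (3.05th percentile, Fisher's exact test, adjusted p = 0.00284). This list shares members with the NRF2 targets, and the same gene gave both medians, so the lists are not separate evidence. The extracellular superoxide dismutase SOD3 fell from 16.7 to 7.87 FPKM, PARK7 from 138 to 73.0 FPKM, sulfiredoxin (SRXN1) from 22.8 to 11.8 FPKM and GLRX2 from 14.4 to 7.35 FPKM. Differences of at least 1 downward were found in 19.0% of NRF2 targets and in 0 of the other antioxidant enzymes, and neither count passed. With random lists matched on transcript length as well, the median of the other antioxidant enzymes stood at the 6.34th percentile.

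Glutathione and ferroptosis genes moved both ways, and neither list was enriched for calls. Of 25 glutathione genes, 13 fell and 8 rose, with a median of -0.17 (12.75th percentile, Fisher's exact test, adjusted p = 0.402 for lower). MGST1 fell from 360 to 126 FPKM, GPX1 from 151 to 71.7 FPKM and GPX2 from 4.35 to 1.17 FPKM. GSTM2, whose reads could be shared with related genes, was called higher at 0.450 and 2.54 FPKM. Of 21 ferroptosis regulators, 13 fell and 6 rose, with a median of -0.22 (15.01st percentile), which did not pass after adjustment (Fisher's exact test, adjusted p = 0.10). Those that fell furthest were SCD, the lipoxygenase ALOX15B (5.16 to 0.571 FPKM), ACSL3 (79.9 to 21.1 FPKM), which activates fatty acids, and the transferrin receptor TFRC (139 to 68.2 FPKM). A difference between these lists and the NRF2 targets was not tested. With an FPKM minimum of 1, 72.2% of ferroptosis regulators were called lower, against 71.4% of NRF2 targets.

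**Figure D3:**
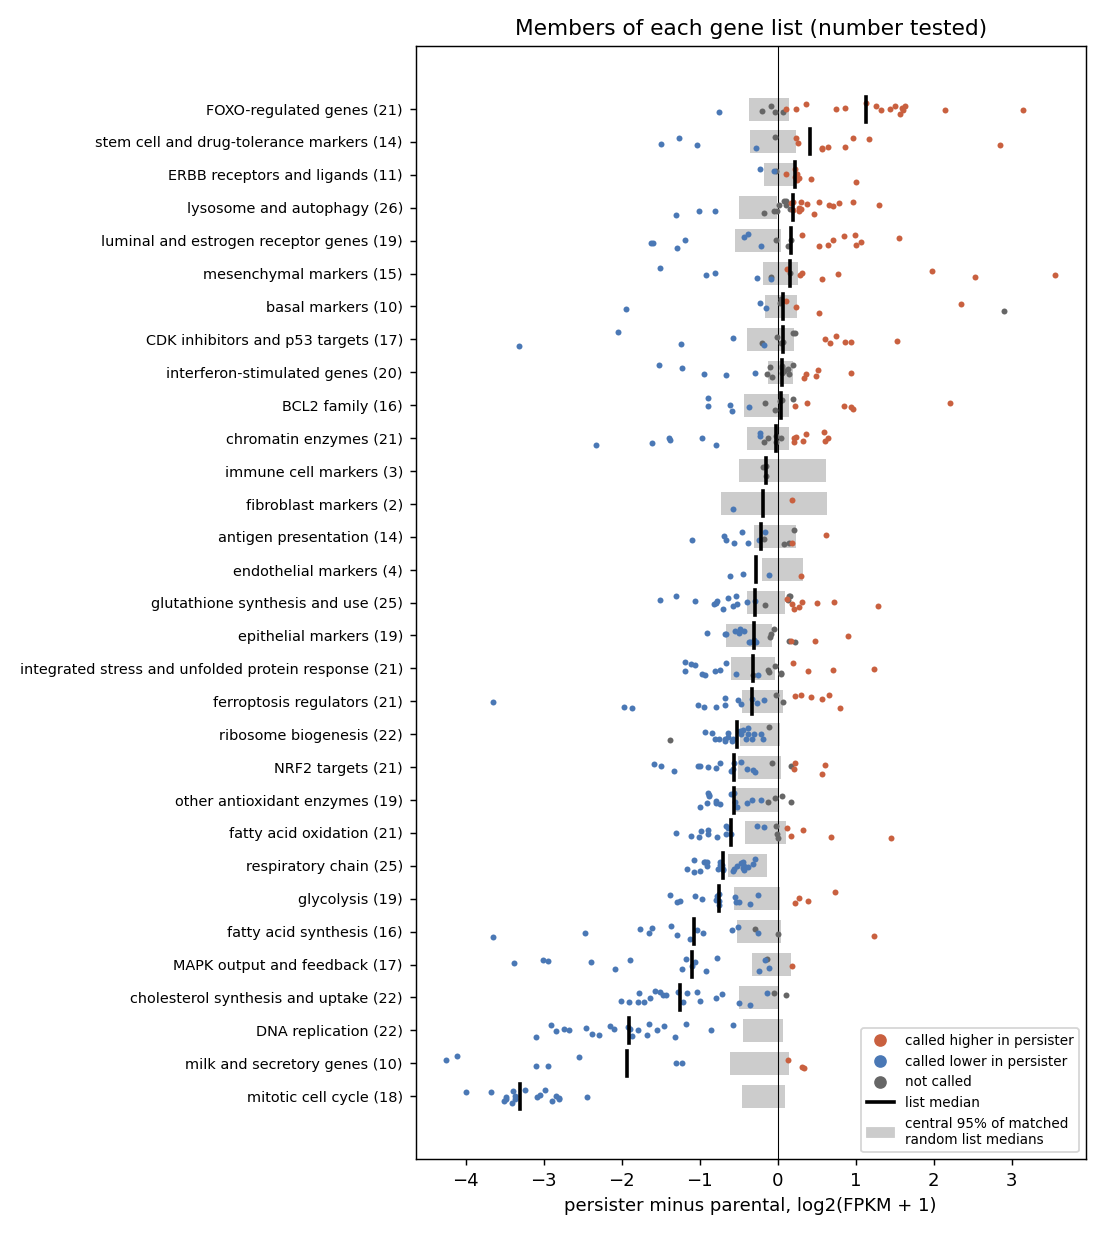
Differences of the tested members of the 31 gene lists, persister minus parental on the log2(FPKM + 1) scale as deposited. Each point is a gene coloured by the call in the authors' deposited table, the black bar is the list median, and the grey band holds the central 95% of medians of 10000 random lists matched on mean FPKM. The mitotic list lies furthest to the left and the FOXO-regulated list furthest to the right.

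Most genes of lipid synthesis were lower. Of 22 genes for cholesterol synthesis and uptake, 20 fell and 0 rose, with a median of -1.13 (Fisher's exact test, adjusted p = 7.29e-06). DHCR7 fell from 68.7 to 16.2 FPKM, MVD from 59.6 to 15.1 FPKM and EBP from 66.1 to 18.5 FPKM. Of 16 genes for fatty acid synthesis, 13 fell and 1 rose, with a median of -0.96 (Fisher's exact test, adjusted p = 0.00440). Beside SCD, the desaturases FADS2 and FADS1 fell from 163 to 28.5 FPKM and from 19.1 to 4.89 FPKM, and fatty acid synthase (FASN) from 298 to 93.8 FPKM. Both medians were below all 10000 matched random lists. Of 21 genes for fatty acid oxidation, 13 fell and 5 rose, with a median of -0.49 (0.05th percentile), while the count of falls did not pass after adjustment (Fisher's exact test, adjusted p = 0.10). ETFA fell from 280 to 113 FPKM, ETFB from 84.7 to 38.5 FPKM and ACAT1 from 28.7 to 13.8 FPKM, and ACADSB rose from 7.45 to 22.1 FPKM.

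Energy metabolism and ribosome assembly were lower by smaller amounts. All 25 respiratory chain genes fell, with a median of -0.59 (0.54th percentile, Fisher's exact test, adjusted p = 3.54e-09), among them NDUFS1 from 33.9 to 14.6 FPKM, CYC1 from 169 to 79.8 FPKM, UQCRC1 from 88.1 to 41.4 FPKM and NDUFA9 from 52.2 to 25.7 FPKM. Of 19 glycolysis genes, 15 fell and 4 rose, with a median of -0.63 (0.08th percentile, Fisher's exact test, adjusted p = 0.00284). Lactate dehydrogenase (LDHA) fell from 70.0 to 26.2 FPKM, hexokinase HK2 from 15.9 to 5.91 FPKM, the lactate exporter SLC16A3 from 9.88 to 3.55 FPKM and ALDOA from 773 to 369 FPKM. Of 22 ribosome biogenesis genes, 20 fell and 0 rose, with a median of -0.41 (1.20th percentile, Fisher's exact test, adjusted p = 7.29e-06), including DKC1 (50.7 to 26.0 FPKM), NOP2 (36.5 to 19.8 FPKM), NOP16 (37.8 to 21.3 FPKM) and RRS1 (41.9 to 24.4 FPKM). With calls limited to differences of at least 1, the respiratory chain list had 12% of its members lower, the glycolysis list 21.1% and the ribosome biogenesis list 0, and none of the 3 passed.

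Lysosome and autophagy genes went the other way. Of 26 tested, 15 rose and 3 fell, with a median of 0.31 (99.98th percentile, Fisher's exact test, adjusted p = 0.0154). GABARAPL1, a protein of the autophagosome membrane, rose from 10.2 to 26.6 FPKM and the protease cathepsin L (CTSL) from 22.1 to 43.9 FPKM, while cathepsin H (CTSH) fell from 36.6 to 14.2 FPKM. Only 3.85% of the list was higher by at least 1, and that count did not pass. In the integrated stress and unfolded protein response list, 11 of 21 fell and 4 rose, with a median of -0.21 (49.63rd percentile, Fisher's exact test, adjusted p = 0.440 for lower). The mTORC1 inhibitor DDIT4 rose from 21.6 to 52.4 FPKM, whereas the serine synthesis enzyme PSAT1 fell from 63.8 to 27.4 FPKM, XBP1 from 643 to 282 FPKM and TRIB3 from 113 to 51.5 FPKM.

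Luminal identity genes moved both ways and milk and secretory genes were mostly lower. Of 19 luminal and estrogen receptor genes, 9 rose and 7 fell, with a median of 0.28 (99.76th percentile) and no enrichment of calls (Fisher's exact test, adjusted p = 0.283 for higher). ESR1, the estrogen receptor gene, rose from 12.4 to 18.2 FPKM (q = 8.82e-10 in the authors' deposited table) and the luminal transcription factor GATA3 from 14.1 to 43.3 FPKM. TFF3 fell from 360 to 116 FPKM, AGR2 from 615 to 203 FPKM and SPDEF from 161 to 65.4 FPKM. Of 10 milk and secretory genes, 7 fell and 3 rose, with a median of -1.81, below all 10000 matched random lists (Fisher's exact test, adjusted p = 0.125 for lower). Beside MUCL1 and SCGB2A2, AZGP1 fell from 134 to 14.7 FPKM and PIP from 29.5 to 2.97 FPKM. Counting only differences of at least 1, the 7 falls in this list did pass (Fisher's exact test, adjusted p = 2.52e-06).

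Epithelial and mesenchymal markers were not enriched for calls in either direction. Of 19 epithelial markers, 11 fell and 3 rose, with a median of -0.20 (63.50th percentile, Fisher's exact test, adjusted p = 0.219 for lower). E-cadherin (CDH1) fell from 143 to 90.0 FPKM, EPCAM from 144 to 89.6 FPKM and CLDN7 from 93.2 to 49.2 FPKM, while plakoglobin (JUP) rose from 116 to 217 FPKM. Of 15 mesenchymal markers, 8 rose and 5 fell, with a median of 0.28 (83.54th percentile, Fisher's exact test, adjusted p = 0.197 for higher). Beside VIM, the transcription factor TWIST1 rose from 2.60 to 19.9 FPKM and tenascin C (TNC) from 3.24 to 15.6 FPKM, and S100A4 fell from 12.4 to 3.70 FPKM. Of 10 basal markers, 4 rose and 3 fell, with a median of 0.19 (60.63rd percentile, Fisher's exact test, adjusted p = 0.703 for higher), led by TRIM29 (2.86 to 18.6 FPKM) and SFN (19.0 to 4.20 FPKM). CDH3 rose from 2.80 to 3.48 FPKM. With genes under 1 FPKM in both groups removed, the basal median was 1.29 as deposited (99.96th percentile), which rests on 4 genes that went both ways: TRIM29, CDH3, SFN and LAMB3, the last named after its values were seen and not called.

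Stem cell and drug-tolerance markers were more often higher, with 9 of 14 up and 4 down and a median of 0.53 (99.91st percentile, Fisher's exact test, adjusted p = 0.0446). IGFBP3 rose from 1.22 to 14.9 FPKM and the aldehyde dehydrogenase gene ALDH1A1 from 15.1 to 35.1 FPKM, while the transcription factors SOX9 and SOX2 fell from 12.9 to 3.93 FPKM and from 1.87 to 0.196 FPKM. The share higher by at least 1 was 14.3% and did not pass. Of 21 chromatin enzymes, 8 rose and 8 fell, and the median was -0.03 as deposited and 0.09 relative to the all-gene median, so its sign depended on scaling (73.49th percentile, Fisher's exact test, adjusted p = 0.681 for higher). Those that fell furthest were UHRF1 (9.67 to 1.13 FPKM), the H3K27 methyltransferase EZH2 (27.9 to 8.41 FPKM) and the DNA methyltransferases DNMT3B (7.14 to 2.09 FPKM) and DNMT1 (58.6 to 21.8 FPKM). In the BCL2 family, 6 of 16 rose and 5 fell, with a median of 0.15 (87.83rd percentile, Fisher's exact test, adjusted p = 0.749 for higher). Among pro-apoptotic members, BMF rose from 4.94 to 26.3 FPKM, HRK from 0.267 to 1.47 FPKM and BBC3 from 8.61 to 17.4 FPKM, and PMAIP1 fell from 8.02 to 3.84 FPKM.

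Interferon-stimulated genes and antigen presentation genes showed no enrichment in either direction. Of 20 interferon-stimulated genes, 5 rose, 5 fell and 10 were not called, with a median of 0.17 (60.14th percentile, Fisher's exact test, adjusted p = 0.437 for lower). IFI6 fell from 5.46 to 1.25 FPKM, USP18 from 14.7 to 5.68 FPKM and OAS3 from 1.61 to 0.356 FPKM, while STAT2 rose from 9.37 to 18.9 FPKM. Of 14 antigen presentation genes, 8 fell and 2 rose, with a median of -0.09 (8.61st percentile, Fisher's exact test, adjusted p = 0.357 for lower). B2M fell from 189 to 116 FPKM. TAP2 was called lower at 5.92 and 2.24 FPKM, HLA-C lower at 156 and 97.8 FPKM and HLA-E higher at 14.5 and 22.9 FPKM, all 3 uncertain because their locus is listed in several copies. With a pseudocount of 0.1 the median of this list was -0.54 as deposited, at the 1.30th percentile.

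Few markers of other cell types were high enough to be tested. Of 10 fibroblast markers, 2 were tested, with COL1A1 lower (13.4 to 8.73 FPKM) and COL6A3 higher (0.0933 to 0.236 FPKM) and a median of -0.08 (25.80th percentile, Fisher's exact test, adjusted p = 0.704 for higher). Of 10 immune cell markers, 3 were tested and 0 were called, with a median of -0.04 (13.52nd percentile, Fisher's exact test, adjusted p = 0.467 for lower). LYZ was at 4.61 and 4.06 FPKM and CD68 at 2.30 and 1.97 FPKM. Of 8 endothelial markers, 4 were tested, with 3 lower and 1 higher and a median of -0.17 (0.75th percentile, Fisher's exact test, adjusted p = 0.487 for lower). All 4 were under 1 FPKM in both groups: CDH5 fell from 0.592 to 0.0441 FPKM, VWF from 0.487 to 0.0884 FPKM and ENG rose from 0.414 to 0.744 FPKM. CLDN5 was called lower at 0.0882 and 0.00610 FPKM, and its difference changed sign relative to the all-gene median.

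Across the 31 lists, 580 distinct genes were in the table and 510 were tested, of which 131 rose and 296 fell. The called-lower share exceeded that of the other tested genes in 10 lists and the called-higher share in 4, with Benjamini-Hochberg adjustment over 62 Fisher's exact tests. Genes within a list are not independent replicates, so these tests and percentiles describe how the lists stand among the other genes. Counts adjusted over the list alone differed in 3 lists: 6 lower in place of 5 among CDK inhibitors and p53 targets, 2 lower in place of 1 among FOXO-regulated genes, and 9 higher in place of 8 among glutathione genes.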

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

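In 145 genes the authors' deposited table gave differing FPKM values for the groups but set the fold to 1 and the q-value to 1, so their test did not cover them. None of these genes entered the counts of called genes or the list tests. In 8 of these genes the persister value was higher by at least 1 on the log2(FPKM + 1) scale and in 14 it was lower by at least 1. Those among the 8 higher genes that are reported here are given because the signal lies outside the tested data, and none has a test behind it.

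PGR, the progesterone receptor gene and a target of the estrogen receptor, was listed at 21.9 FPKM in parental and 128 FPKM in persister cells, a difference of 2.49. NRP1, a co-receptor for semaphorins and VEGF, was listed at 2.64 and 22.0 FPKM, a difference of 2.66. The difference was 2.09 for GATS, 1.89 for THBS3, which encodes thrombospondin 3, and 1.38 for the scaffold protein gene NEDD9. It was 1.04 for the phosphate transporter gene SLC34A3. Among those lower in persister cells, and named after their values were seen, were genes listed at exactly 0 there despite high parental values, such as RPL23 (5076 FPKM) and IGFBP5 (304 FPKM).

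Exact zeros in both groups formed a pattern of their own, at 1527 rows. In the major histocompatibility complex, 129 of 256 rows (50.4%) were at 0 in both groups, against 1398 of the 18547 other rows (7.54%), a ratio of 6.69 (Fisher's exact test, p = 3.99e-72). Of those 129 rows, 124 carried the symbol of another row above 0, which is consistent with reads being assigned to 1 of several copies of this locus in the genome build, and 5 of its 130 genes had every row at 0. For ERBB2, a failure of the whole amplified neighbourhood from deep coverage was tested next: 0 of the 20 nearest coding genes, 10 on either side, were at 0 in both groups or without an estimate, which argues against it. The zero of ERBB2 itself stays open, and no biological explanation was tested. A wider look made after that result placed RPL19 (11 places away) and LASP1 (16 places) at 0 in both groups and RPL23 (17 places) without an estimate. Further out, KRT26 (29 places), KRTAP3-3 (38 places) and KRTAP3-2 (39 places) were at 0 in both groups and SYNRG (34 places) had no estimate. Outside the major histocompatibility complex 7.54% of rows were at 0, and 0.771% of all rows had no estimate. Those shares take in genes of any expression level, silent ones included, so they cannot decide whether these genes show a local failure.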

How the results depend on the processing

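No paired analysis was possible because the table's columns carry no replicates. For the same reason, leaving out single libraries, a replicate block, quantile normalization, a count model, an estimated correlation and a test with a pseudocount of 0.1 were not run. Depth per library is unknown, so how far it limits any result could not be measured. Random lists matched on transcript length as well and the count over every row of the table were chosen only after the data were seen. Centring on the all-gene median cannot change the count of 9514 called genes. That count stayed within 1.5 times under a q-value of 0.01, an FPKM minimum of 1 and use of every row. It was 1225 (406 higher, 819 lower) with a minimum difference of 1 and 6157 (2096 higher) with an FPKM minimum of 5, both by construction, since fewer genes can pass. Centring moved the share of calls that were lower from 55.8% to 54.9%. Over all settings, 229 list results stayed on the same side of their threshold, and 8 lost a pass, 3 gained it and 2 reversed. A change of sign counted as reversed only where the main result had passed. The chromatin enzyme median, which changed sign with centring, is thus among the 229. By construction, centring kept the percentiles of all 31 list medians. Matching on length affected the Fisher results only through genes without a known length. A minimum difference of 1 ended the higher share of the ERBB (9.09%), lysosome and autophagy (3.85%) and stem cell and drug-tolerance (14.3%) lists, and the lower share of NRF2 targets (19.0%), glycolysis (21.1%) and the respiratory chain (12%). It took other antioxidant enzymes and ribosome biogenesis to 0, under the share of other genes, because the differences of their called members were all under 1. The milk and secretory list passed under it, at 70% lower. The ERBB list median as deposited was 0.41 with a pseudocount of 0.1 and 0.25 with an FPKM minimum of 1, inside the central 95% of matched lists in both cases. The basal median was 1.29 with that minimum, over the 4 genes left, and the antigen presentation median -0.54 with that pseudocount, both then outside it. The cause of these list median changes was not tested. Of the named genes' results, 269 kept their direction. In the 135 with a pseudocount of 0.1 this was fixed by construction, since a pseudocount cannot change the sign. With centring 134 kept it. CLDN5 reversed to 0.00236 after centring, which by construction adds the all-gene shift to a near-zero difference.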

Other observations

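Gene families outside the fixed lists were chosen after the data were seen, and their tests share that limit, while the tests of explanations below were set out before their results were seen. Collagens were mostly higher in persister cells, with 18 of 27 tested genes called higher and 5 lower in the authors' deposited table and a median of 0.45 relative to all genes (Fisher's exact test, adjusted p = 4.87e-04). COL12A1 rose from 14.3 to 85.7 FPKM, COL18A1 from 3.54 to 10.7 FPKM and COL7A1 from 1.39 to 6.03 FPKM. Protocadherins, adhesion proteins of the cadherin superfamily, were higher in 18 of 20 (median 0.30, Fisher's exact test, adjusted p = 3.25e-07), most of them from values under 1 FPKM, such as PCDH7 from 0.0967 to 1.32 FPKM. Semaphorins and plexins, guidance ligands and their receptors, were higher in 17 of 26 and lower in 2 (median 0.33, Fisher's exact test, adjusted p = 9.01e-04), led by SEMA5A (0.443 to 5.47 FPKM) and SEMA6C (0.382 to 4.61 FPKM), and once transcript length was matched as well their median stood at the 96.93rd percentile, inside the central 95%. Zinc finger genes of the ZNF series were higher in 198 of 427 and lower in 87 (median 0.25, Fisher's exact test, adjusted p = 1.03e-10). Krüppel-like factors had 6 of 13 higher and 3 lower (median 0.23, Fisher's exact test, adjusted p = 0.307). Solute carriers had 71 of 223 higher and 88 lower, with a median of -0.03 as deposited and 0.08 relative to all genes (Fisher's exact test, adjusted p = 0.850 for higher).

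CEACAM6, an adhesion molecule of luminal epithelium, fell from 424 to 34.1 FPKM, and 6 of 8 CEACAM genes, which share sequence, were called lower (median -1.75), a count that did not pass (Fisher's exact test, adjusted p = 0.0915). In the S100 family of calcium-binding proteins, 11 of 14 fell and 1 rose (median -0.94, Fisher's exact test, adjusted p = 0.00762), among them S100P (407 to 90.9 FPKM) and S100A14 (337 to 91.6 FPKM). Tubulins, led by TUBA1B (666 to 180 FPKM), had 12 of 19 lower (median -0.57), a count that did not pass either (Fisher's exact test, adjusted p = 0.0539). Nuclear pore genes were lower in 17 of 20 (median -0.46, Fisher's exact test, adjusted p = 1.26e-04). Histone genes, many of them near-identical, were lower in 42 of 71 and higher in 8 (median -0.26, Fisher's exact test, adjusted p = 0.00181). The libraries were made from polyadenylated RNA, so histone transcripts without a poly(A) tail would be missed. Aminoacyl-tRNA synthetases were lower in 20 of 32 (median -0.18, Fisher's exact test, adjusted p = 0.0176), and proteasome subunits in 34 of 37 (median -0.38, Fisher's exact test, adjusted p = 1.38e-10), though both medians lay inside the central 95% of matched lists (22.38th percentile for the synthetases and 5.83rd for the proteasome). LAMB3, a basal marker encoding a laminin chain, was listed at 0.648 and 11.3 FPKM and COL17A1 at 1.12 and 8.21 FPKM, and neither was called, with q-values of 0.381 and 0.160 in the authors' deposited table.

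Metabolic and antioxidant transcripts fell in a background where short and abundant transcripts fell more. Among the 10% of genes with the shortest transcripts the median difference as deposited was -0.43, against 0.09 among the 10% with the longest. A trend with length and abundance as the whole cause was argued against for the respiratory chain list, whose median stood at the 1.08th percentile of random lists matched on both, and for glycolysis, at the 0.07th percentile. For the other antioxidant enzymes this test decides nothing, since the median was inside the central 95% of lists matched on mean FPKM alone (3.05th percentile) as well as of those matched on both (6.34th percentile). A single scaling factor was argued against by the cytosolic ribosomal proteins, which are shorter and more abundant than the respiratory chain genes: on the scale as deposited, their median was 0.02 (interquartile range -0.07 to 0.18, with 20 of 76 higher and 11 lower), that of the respiratory chain -0.71 (interquartile range -0.91 to -0.45), a gap of 0.724. Mitochondrial ribosomal proteins fell in 68 of 75 with 0 higher (median -0.63 as deposited).

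The rise of CYP1A1 could reflect a rise of aryl hydrocarbon receptor targets as a group. Of the 7 other tested targets, 2 were called higher (28.6%) and 3 lower, with a median of -0.07 as deposited, which argues against a rise of the whole group. CYP1A2, a neighbour and close relative of CYP1A1, rose from 0.00803 to 0.438 FPKM and TIPARP from 9.84 to 16.9 FPKM. The receptor's repressor AHRR fell from 290 to 193 FPKM, NQO1 from 96.7 to 55.7 FPKM and LRAT from 0.264 to 0.180 FPKM. CYP1A2 and LRAT were under 1 FPKM in both groups, so the test rests on few well-expressed genes. Reads from overlapping genes cannot be told apart in these libraries, which leaves the high AHRR value uncertain. With CYP1A1 included, the list had 3 of 8 higher and 3 lower, and its median was -0.02 as deposited and 0.10 relative to all genes (Fisher's exact test, adjusted p = 0.810 for higher). What raised CYP1A1 stays open.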
